A study of Homo sapiens with 6 samples.

How the data were processed

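Messenger RNA was sequenced from QBC-939 cells, a human line that the labels describe as cholangiocarcinoma (cancer of the bile duct), in 3 control libraries and 3 libraries made after knockdown of ANXA10 (annexin A10) with a short hairpin RNA. The identity of the line was not tested here. Per the labels' protocols, RNA was extracted with Trizol from frozen cells and libraries were made with an Illumina TruSeq kit. Per the submitters' processing notes, CASAVA 1.8 and HISAT2 were used with the hg19 genome. The program that turned alignments into gene values, its annotation release and its handling of strand are not given in the sources used here. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

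The deposited table held 1 row for each of 20307 protein-coding genes, with 1 further line emptied of its content. Per the file headers, the authors gave each library FPKM (fragments scaled to gene length and depth) and a count column. The count columns hold estimated counts that the authors deposited after a scaling by 1 factor per library: low values were whole multiples of 1 number, between 0.835 (knockdown library 3) and 1.12 (control library 2). The deposited totals were close to each other, from 14058732 to 14571169, as such a scaling would give. Each column was divided by its own number and rounded to whole reads. Between 78.7% and 87.5% of the values of a library lay within 0.02 of a whole read before rounding, and the others were fractional estimates. The recovered totals were 13218338, 12950916 and 15972138 reads for control libraries 1, 2 and 3 and 13361421, 14214838 and 16837142 for knockdown libraries 1, 2 and 3. No pair of libraries held identical values.

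The column names of the table are S1 to S3 and N1 to N3, and match no title word for word. S was read as the short hairpin RNA and N as the negative control, before any ANXA10 value was viewed, and the direction of each change reported here rests on that reading. All per-sample columns of the table were used. Deposited positions are hg19 loci, of which 7899 are shared with another gene, so reads of overlapping genes may have been divided by an estimate. There were 149 rows whose symbol occurs more than once. Ribosomal protein and histone genes have near-identical copies, and their single values are uncertain for that reason.

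The comparison was knockdown minus control, fitted with edgeR 4.0.16 in R 4.3.3: TMM normalisation, the filterByExpr filter (minimum count 10, minimum total 15) and the quasi-likelihood F test, two-sided, over 12480 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 change was its size divided by the square root of F. Levels are TMM-normalised counts scaled to library size (CPM). The 36 gene lists were fixed before the data were examined and the 35 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists. Camera was repeated with an estimated correlation, and fry was run on the same lists. Exact permutation tests were used for ANXA10 and PLA2G4A, where 3 libraries against 3 cannot give a two-sided p below 0.1.

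Named genes followed a rule fixed in advance: ANXA10 and PLA2G4A; the 10 largest rises and falls among genes past the threshold without overlap between groups, or the 5 smallest p where fewer than 3 passed; and up to 4 members of each list past the threshold, or the 2 with the smallest p. Up to 3 of the highest members of each cell type list were added. Names outside that rule are marked where they occur, and 1 gene that the rule names is not reported here.

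Tested on simulated data with the dispersions of these libraries and 12480 genes, the same steps called 17.9% of 67 genes changed 2-fold, 94.0% of 67 changed 4-fold and 98.5% of 66 changed 16-fold, with 6 false calls, and 0 genes when nothing was changed. Camera called the list raised 2-fold and 0 of the others. The simulated genes varied independently of each other, so this could not show false list calls that come from genes varying together.

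Library deviations from their group means correlated at 0.158, 0.391 and 0.536 for the numbers 1, 2 and 3, all above 0.1, so the numbers were taken to pair the libraries. The labels name no shared day or batch. Library 1 of each group correlated best with number 2 of the other, at 0.269 for control library 1 and 0.274 for knockdown library 1. With 3 libraries per group, libraries 3 standing apart can by itself make the others correlate positively. These values therefore do not show that libraries 1 and 2 pair by number. Alternatives planned in advance were no filter on low counts, a mean of at least 5 CPM, DESeq2 size factors, DESeq2 1.42.0, the replicate number as a block, each library left out in turn, an estimated correlation and fry. Those added after seeing the data were limma with trend on log2 of FPKM plus a pseudocount of 1, 0.5 or 0.1, the deposited scaled counts, libraries 3 of both groups left out, the first principal component of the residuals as a covariate, genes listed at 0 left out, and the estimated correlation within the block and left-out settings. Transcript length and GC content came from GENCODE v29 transcripts, matched by Ensembl gene identifier for 19497 genes and used for no coordinate. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used to prepare the table and draw figures.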

Results

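Expression was measured by mRNA sequencing in 6 libraries of QBC-939 cells, 3 control and 3 with ANXA10 knocked down by a short hairpin RNA. Depth ran from 12950916 reads in control library 2 to 16837142 in knockdown library 3. The series title concerns the part of annexin A10, a calcium-dependent phospholipid-binding protein, in invasion of these cells. The comparison asks which mRNAs differ once ANXA10 is lowered.

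ANXA10 was lower in the libraries read as knockdown than in those read as control, without overlap between groups. Its level was 184 ± 52.6 TMM-normalised read counts scaled to library size (CPM) in control and 88.5 ± 46.1 CPM in knockdown libraries (SD, n = 3 each), 48.0% of the control mean. The control libraries 1, 2 and 3 held 218, 211 and 124 CPM, and the knockdown libraries 112, 118 and 35.3 CPM. PLA2G4A, which encodes cytosolic phospholipase A2, was 47.4 ± 6.60 CPM in control and 32.5 ± 3.85 CPM in knockdown libraries (SD, n = 3 each), again without overlap. The log2 change was -1.06 (SE 0.46) for ANXA10 and -0.54 (SE 0.19) for PLA2G4A. Neither passed adjustment in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.794 for both, unadjusted 0.0526 and 0.0233). Both exact permutation tests gave a two-sided p of 0.1, the smallest that 3 against 3 allow. On the authors' FPKM scale ANXA10 was 141 ± 33.9 in control and 61.5 ± 27.3 in knockdown libraries (SD, n = 3 each). The deposited hg19 locus of ANXA10 (ENSG00000109511) is chromosome 4, 168867825 to 169108841, and that of PLA2G4A (ENSG00000116711) is chromosome 1, 186798085 to 186958113. PLA2G4A passed without knockdown library 3 (log2 change -0.64, adjusted p = 0.0214 in edgeR), whereas ANXA10 did not (-0.68, adjusted p = 0.0558). In that setting 2140 genes were higher and 2021 lower of 12593 tested. With libraries 3 of both groups left out, a setting added later, both passed in edgeR, at -0.91 for ANXA10 (adjusted p = 0.0012) and -0.75 for PLA2G4A (adjusted p = 0.00338). That fit compared 2 libraries with 2, and 2469 genes were higher and 2255 lower of 12450 tested. A pass in either setting was thus common and not particular to these genes. Over all settings the adjusted p of edgeR, DESeq2 or limma ran from 0.000162 to 0.999 for ANXA10 and from 0.00338 to 1.00 for PLA2G4A. The 0.000162 came from an edgeR fit with a covariate drawn from the residuals of these same libraries, which lowers their spread by construction.

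**Figure D1:**
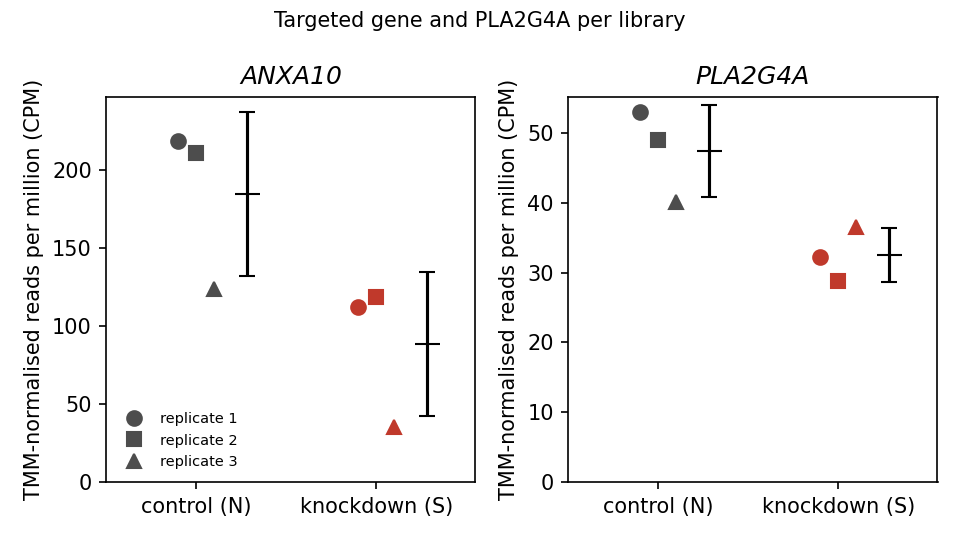
ANXA10 and PLA2G4A in TMM-normalised CPM (vertical axes, from 0) for each control and knockdown library; marker shape is the replicate number and the bar is the mean with its SD (n = 3). ANXA10 lay between 124 and 218 CPM in control and between 35.3 and 118 CPM in knockdown libraries.

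Several genes of the extracellular matrix rose in the knockdown libraries from low control levels. COL3A1, a fibrillar collagen chain, rose from 3.35 ± 0.496 to 98.8 ± 53.3 CPM (SD, n = 3 each; log2 change 4.89, SE 0.48). VCAN, the matrix proteoglycan versican, rose from 3.01 ± 1.19 to 71.0 ± 26.5 CPM, and TIMP3, an inhibitor of metalloproteinases, from 0.597 ± 0.314 to 37.8 ± 23.3 CPM (SD, n = 3 each). The collagen-binding proteoglycans DCN (log2 change 5.13, SE 0.51) and LUM (5.07, SE 0.68) rose as well, as did SPARC (5.07, SE 0.42), COL6A3 (5.08, SE 0.55) and FBN1 (4.96, SE 0.59). CDKAL1, a tRNA-modifying enzyme, had the highest control level among the genes that rose and went from 15.9 ± 2.06 to 48.1 ± 5.59 CPM (SD, n = 3 each; log2 change 1.60, SE 0.19). Genes that are not of the matrix rose as well. PGR went from 1.22 to 30.5 CPM, MUC16 from 1.11 to 28.1 CPM and PAEP from 0.62 to 10.5 CPM. VCAN, CDKAL1, PGR, MUC16 and PAEP lie outside the naming rule and were chosen after their values were seen. Whether these rises came from the cells themselves or from RNA of another tissue was not settled, as set out under the other observations.

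In all, 29 of 12480 tested genes were higher and 0 lower at an adjusted p below 0.05 (edgeR, Benjamini-Hochberg). All 29 were higher in each knockdown library than in each control library, 24 had a control mean below 1 CPM, and their median was 16 control and 424 knockdown reads over 3 libraries each. At an unadjusted p below 0.05 there were 437 higher and 245 lower genes, and 10.8% of all genes showed no overlap between groups, where chance gives 10%. TUB had 1 control read against 109 in knockdown, a ratio of 110 with a 95% counting interval of 19.3 to 4382. A2M, the plasma protease inhibitor, had 2 against 235 reads (ratio 119, interval 32.4 to 984), and NPAS3 had 2 against 93 (46.9, interval 12.6 to 393). These intervals are exact binomial ones and cover counting error only. With the replicate number as a block, 65 genes were higher and 2 lower, with 28 of the 29 kept. DESeq2 called 146 higher and 27 lower, and limma on FPKM 2 higher and 0 lower. No gene passed without control library 1, 2 or 3, 1 was higher and 1 lower without knockdown library 1, 92 higher and 0 lower without knockdown library 2, and 2140 higher and 2021 lower without knockdown library 3; all 29 were among the higher genes in both of the last settings.

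**Figure D2:**
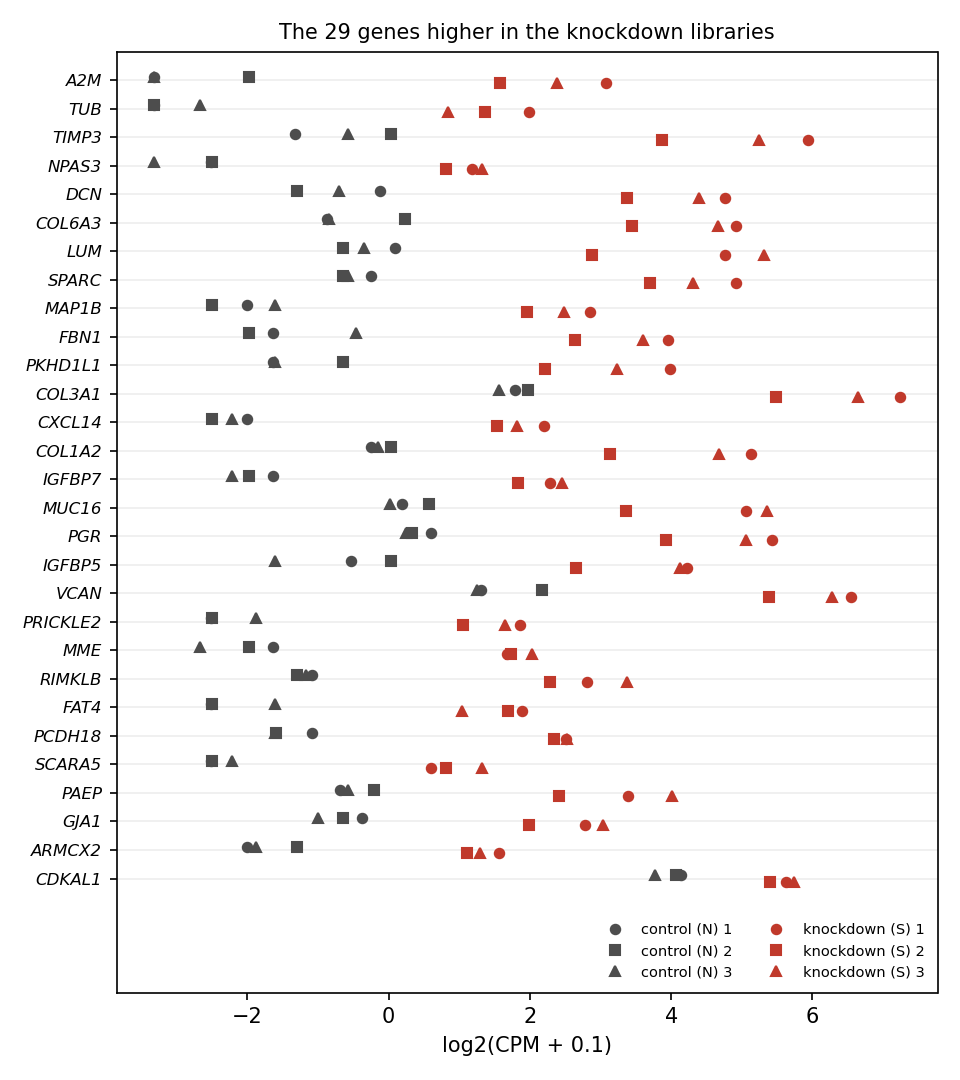
The 29 genes higher in the knockdown libraries, with log2 of CPM plus 0.1 on the horizontal axis and 1 marker per library (grey, control; red, knockdown; shape, replicate number). For each gene the 3 knockdown libraries lie above the 3 control libraries, and for 25 of the 29 knockdown library 2 is the lowest of the knockdown libraries. The same held for a share of 0.362 of all tested genes.

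Among the lower genes with the lowest p-values were CLDN18, a tight junction claudin, USP25, a deubiquitinating enzyme, EMP1 and ITGB7, none of which passed. CLDN18 was 9.51 ± 1.52 CPM in control and 1.76 ± 0.759 CPM in knockdown libraries (SD, n = 3 each; log2 change -2.40, SE 0.37, edgeR adjusted p = 0.0644). USP25 had a log2 change of -1.50 (SE 0.26, edgeR adjusted p = 0.0873), EMP1 of -1.19 and ITGB7 of -1.50. With the replicate block CLDN18 and USP25 passed, at edgeR adjusted p = 0.0433 and 0.0446.

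Fibroblast markers and mesenchymal genes stood out most among the fixed lists. Of 10 tested fibroblast markers 4 rose (COL3A1, DCN, LUM and COL1A2) and 7 rose adjusted over the list alone; the median log2 change was 3.79. Of 21 tested mesenchymal genes 5 rose, SPARC and the same 4 genes, and 10 rose adjusted over the list alone. Camera gave adjusted p = 6.9e-35 and 5.96e-29, but adjusted p = 0.0631 and 0.0862 with an estimated correlation. Fibroblast markers summed to 14.4 ± 1.28 CPM in control and 196 ± 98.2 CPM in knockdown libraries (SD, n = 3 each). The tested mesenchymal genes summed to 437, 416 and 510 CPM in control libraries 1, 2 and 3. They summed to 645, 353 and 816 CPM in knockdown libraries 1, 2 and 3, so that knockdown library 2 lay below every control library. VIM, the mesenchymal intermediate filament vimentin, had a log2 change of 2.02 that did not pass over all genes (edgeR adjusted p = 0.194) but passed with the replicate block (1.99, edgeR adjusted p = 0.046) and without knockdown library 3 (2.00, edgeR adjusted p = 0.00968); it lies outside the naming rule. The mesenchymal median, 1.33, ran from 0.87 to 2.29 with 1 library left out. With the block 6 fibroblast markers and 9 mesenchymal genes rose over all genes. Among blood markers HBB, a globin chain, had 3, 0 and 0 reads in the control and 166, 44 and 240 in the knockdown libraries, and missed the threshold (edgeR adjusted p = 0.0504), but passed with the replicate block (log2 change 7.08, edgeR adjusted p = 0.00601). Of 23 tested proteases and inhibitors TIMP3 rose, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000618, 0.15 with an estimated correlation, 0.194 without knockdown library 3), and 3 rose over all genes with the block; their median, 0.32, ran from 0.26 to 0.55 with 1 library left out.

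Ribosomal protein genes were higher on balance, with a positive log2 change in all 72 and a median of 0.54, though no single one passed. RPS29 had a log2 change of 1.27 (SE 0.68). The lists of the nuclear-encoded respiratory chain (median 0.44 over 38 genes), heat shock response (0.60 over 21), G1/S and replication (0.27 over 32) and replication-dependent histones (1.15 over 16) were also called up, with camera adjusted p of 2.15e-05 for ribosomal proteins, 0.00186, 0.000447, 0.00294 and 2.1e-08. None of these calls held with an estimated correlation, where the adjusted p was 0.806 for ribosomal proteins, the respiratory chain and G1/S, 0.77 for heat shock and 0.38 for histones. No member passed over all genes, and 2 histones, HIST1H4H (log2 change 2.35) and HIST1H4E (2.54), passed adjusted over the list alone. MCM6, a replicative helicase subunit, had a log2 change of 1.03 and HSPA1A, an inducible chaperone, of 0.89. Ribosomal protein mRNA took 9.78%, 10.11% and 6.75% of the reads in control libraries 1, 2 and 3 and 12.41%, 14.6% and 6.47% in knockdown libraries 1, 2 and 3, so that knockdown library 3 lay below every control library. Those shares cover symbols that begin with RPL or RPS and a digit, not exactly the 72 listed genes. Without knockdown library 2 the adjusted p was 0.902 for ribosomal proteins and for the respiratory chain, 0.157 for heat shock and 0.363 for G1/S. Without knockdown library 1 it was 0.0943 for the respiratory chain and 0.136 for G1/S, and without control library 3 it was 0.147 for ribosomal proteins and 0.325 for the respiratory chain. With 1 library left out the medians ran from 0.15 to 0.89 for ribosomal proteins, 0.14 to 0.78 for the respiratory chain, 0.36 to 0.90 for heat shock and 0.13 to 0.44 for G1/S, in each case lowest without knockdown library 2 and highest without knockdown library 3.

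Epithelial junction genes and genes of the unfolded protein and amino acid stress response were called down. Of 24 junction genes 19 had a negative log2 change, with a median of -0.20 (camera adjusted p = 0.00548, 0.486 with an estimated correlation), and no member passed; OCLN, the tight junction protein occludin, had -0.62 and DSC2, a desmosomal cadherin, -0.53. Of 31 stress response genes 21 were negative, with a median of -0.24 (camera adjusted p = 0.000798, 0.38 with an estimated correlation). None of them passed singly; DDIT3, a stress-induced transcription factor, had a log2 change of -1.15 and ATF5 of 1.62. Both list calls held with each library left out in turn, but the medians ran from -0.40 to -0.11 and from -0.39 to -0.19. The most negative median of each came without knockdown library 3, where 10 junction genes were lower and 1 higher over all genes (camera adjusted p = 0.00222, 0.407 with an estimated correlation). The list of mitochondrially encoded mRNAs was called down (camera adjusted p = 0.0139, 0.77 with an estimated correlation), but 8 of its genes were listed at 0 in knockdown library 3. MT-CO3, chosen after its values were seen, had 120999, 136629 and 168252 reads in control libraries, 187876 and 161975 in knockdown libraries 1 and 2, and was listed at 0 in knockdown library 3. Without that library the list pointed up (median 0.16) and did not pass (adjusted p = 0.651), and without control library 3 it did not pass (0.0532).

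**Figure D3:**
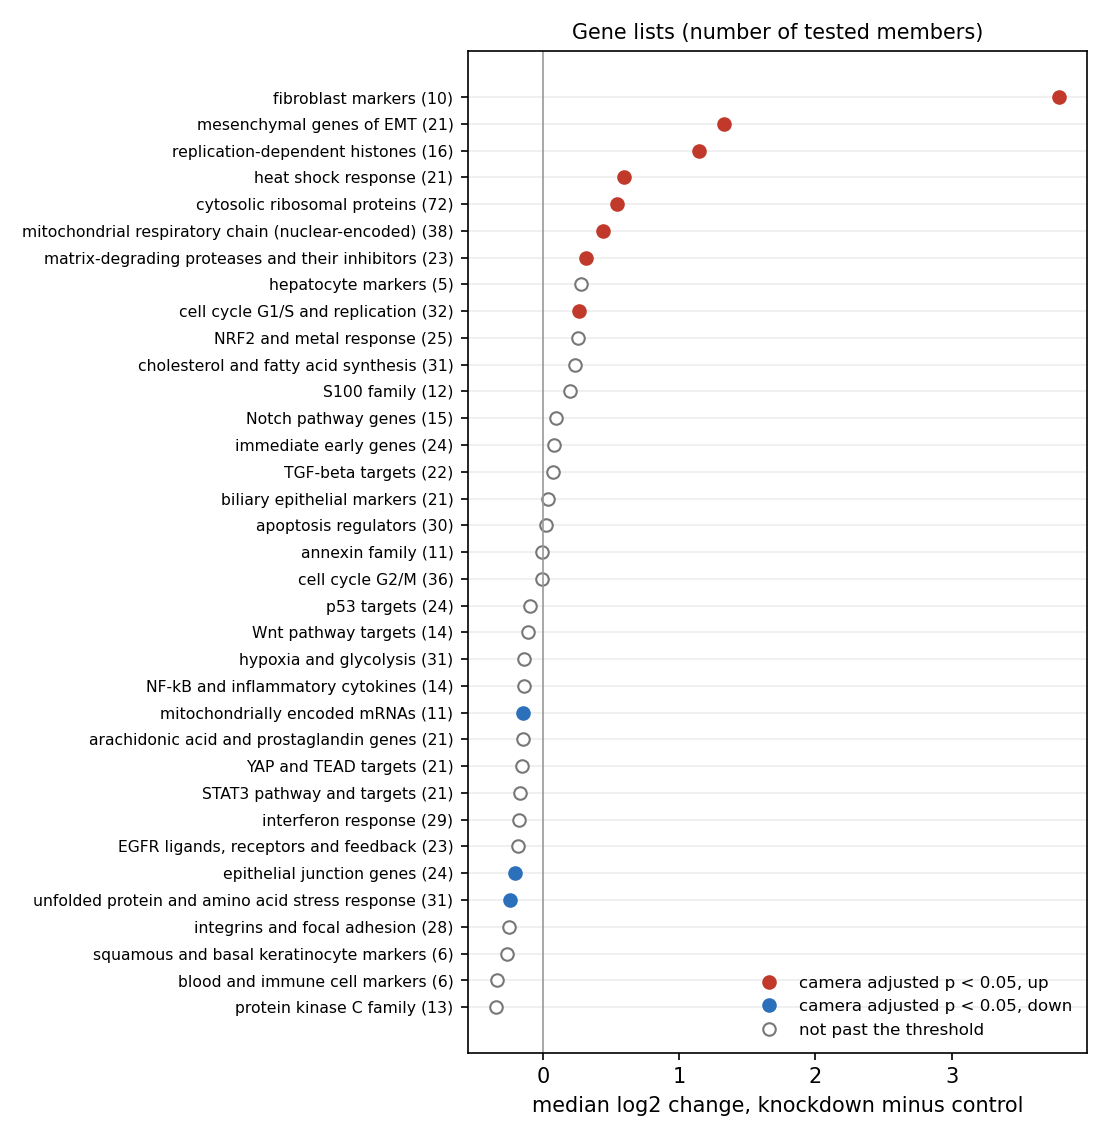
Median log2 change, knockdown minus control (horizontal axis), of the 35 tested gene lists, with the number of tested members in brackets; red and blue points passed camera with a preset correlation, upward and downward, and open points did not. Fibroblast markers had the largest median, 3.79, and 0 of the lists passed with an estimated correlation; the mitochondrially encoded list pointed up without knockdown library 3.

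The remaining 24 lists did not pass camera over all 6 libraries. Camera adjusted p was 0.104 for integrins and focal adhesion, 0.119 for the protein kinase C family, 0.118 for EGFR ligands and feedback, 0.131 for STAT3 targets, 0.221 for inflammatory cytokines, 0.243 for the interferon response and 0.719 for TGF-beta targets. It was 0.394 for YAP targets, 0.644 for Wnt targets, 0.901 for Notch genes, 0.991 for G2/M genes, 0.406 for p53 targets, 0.901 for apoptosis regulators, 0.239 for hypoxia and glycolysis and 0.221 for lipid synthesis. Annexins had 0.901, S100 genes 0.406, arachidonic acid genes 0.738, metal response genes 0.119, immediate early genes 0.938, biliary markers 0.901, squamous markers 0.0501, hepatocyte markers 0.369 and blood markers 0.588. Integrins passed downward with the replicate block (camera adjusted p = 0.0217, 0.774 with an estimated correlation). Without knockdown library 3 camera called integrins (adjusted p = 2.88e-05), the protein kinase C family and EGFR ligands and feedback (0.0127 each) down, and metal response genes (0.000654) and S100 genes (0.03) up; with an estimated correlation none of these held (adjusted p = 0.702 for S100 genes and 0.576 for the others). Over all libraries by fry the interferon response passed downward (adjusted p = 0.032), the only list to do so; camera with an estimated correlation gave adjusted p = 0.756. Of its 29 tested members 18 were negative, and the only one to pass adjusted over the list alone pointed the other way, XAF1, an interferon-induced apoptosis factor, with 2 control and 56 knockdown reads (log2 change 4.70, edgeR adjusted p = 0.122 over all genes). Among arachidonic acid genes PTGS1, a cyclooxygenase, had a log2 change of -0.83 that did not pass. Only 2 of 14 endothelial markers were expressed highly enough to test, ESAM (log2 change -0.42) and ENG (0.16), and neither passed. KRT8 and KRT18, keratins of simple epithelia, were at 3007 ± 129 and 2397 ± 199 CPM in control libraries (SD, n = 3) and did not pass. In MUC5AC, a secreted mucin on the biliary list, the log2 change was -1.66, and in TFF3, a mucosal peptide on that list, 2.18; both passed adjusted over the list alone.

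**Figure D4:**
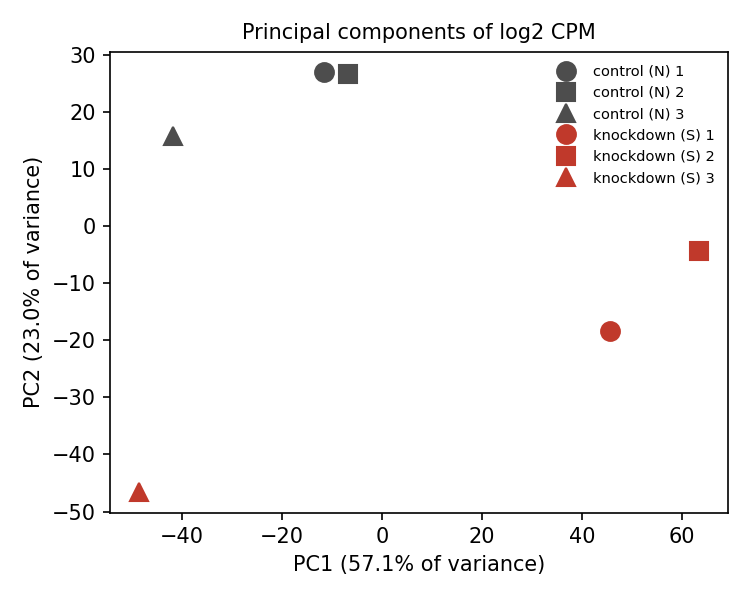
Principal components of log2 CPM over the tested genes, PC1 on the horizontal and PC2 on the vertical axis, with their share of variance; colour is the group and shape the replicate number. PC1 took 57.1% of the variance and set libraries 3 of both groups, at -41.8 (control) and -48.7 (knockdown), apart from knockdown libraries 1 and 2, at 45.5 and 63.6.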

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

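The limma, scaled-count, library 3, covariate and listed-at-0 settings were chosen after the results were seen. The number of higher genes (29) moved to 5 with a mean of at least 5 CPM, where fewer genes were tested, to 146 with DESeq2 (27 lower), to 65 with the replicate block (2 lower), and to 2 with limma on FPKM at each pseudocount. It became 2469 (2255 lower) with libraries 3 of both groups left out and 1483 (1404 lower) with the residual component, and ranged from 0 to 2140 higher and 0 to 2021 lower with 1 library left out. It was 34 without a filter, with DESeq2 size factors and without genes listed at 0, and 28 on deposited counts. The change of ANXA10 passed at -0.91 and -1.20 with libraries 3 left out and with the residual component, and that of PLA2G4A at -0.75 and -0.55. That component was taken from the deviations of these same libraries, so it lowers the residual spread by construction. Its passes and its larger number of called genes are therefore no independent evidence. With 1 library left out the change ranged from -1.34 to -0.68 for ANXA10 and from -0.66 to -0.46 for PLA2G4A. Adjusted p ranged from 0.000162 to 0.999 for ANXA10 over these settings. Lists past the threshold went from 11 to 0 with an estimated correlation and 1 with fry, and stayed between 9 and 14 otherwise. With 1 library left out the log2 change turned sign in PKP1 (-0.44 to 0.07), SPINT2 (-0.04 to 0.38), SFN (-0.05 to 0.72) and the median of the mitochondrially encoded list (-0.55 to 0.16, and 0.33 without libraries 3), and by limma in ENG (-0.05, -0.06 and -0.05); no turned value passed. For the other named genes 1274 values kept direction and side, 196 passed newly and 80 no longer passed; for the lists called, 168 held and 38 no longer passed. Among genes named by the rule the replicate block changed the calls of CLDN18, USP25 and HBB only, each to a pass, and among lists that of integrins. The cause was not tested, except that the listed zeros of knockdown library 3 drop out with it. Planned quantile, other limma and pseudocount settings on normalised values and the transcript setting did not apply to gene counts and were not run. At this depth and spread a 2-fold change was mostly missed, as the simulated data showed.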

Other observations

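The test on markers with few reads, the splits with the replicate block, the estimated correlation in the setting without knockdown library 3, the count of genes lowest in 1 library, the judgement that an earlier bound was wrong and the choice of the genes named in this part outside the naming rule came after the results were seen. The planned setting without knockdown library 3 compared 3 control with 2 knockdown libraries. In it, genes of several fixed lists passed edgeR's test that did not pass over all libraries. The library left out had the lowest ANXA10 of the knockdown libraries, 35.3 CPM against 112 and 118 CPM. Over all genes 2140 of 12593 were higher and 2021 lower, the shares against which the list counts stand. Camera with an estimated correlation called none of the lists in that setting (adjusted p = 0.576 for stress response, integrin, EGFR and ribosomal protein genes, 0.326 for heat shock and G1/S genes). Of 31 stress response genes 12 were lower and 3 higher, the lower ones including DDIT4, an mTORC1 inhibitor (log2 change -2.86), CHAC1 (-2.21), SESN2 (-1.51) and ATF3 (-1.43), the higher ones ATF5 (2.05). Of 28 integrin and focal adhesion genes 15 were lower and 0 higher, including ITGA2 (-1.46), LAMB3 (-1.04) and ITGA6 (-1.02). Of 23 EGFR ligands and feedback genes 9 were lower and 1 higher, with the ligands AREG at -2.23 and EREG at -1.06. Chaperones went the other way, 12 of 21 heat shock genes higher and 0 lower, with HSPE1 at 1.82 and HSPA8 at 1.38, and G1/S genes were 14 higher and 0 lower of 32, with CCNE2 at 1.51. Arachidonic acid genes went both ways, 4 higher and 4 lower of 21, close to the shares over all genes. That list did not pass camera (adjusted p = 0.846). PTGS2, the inducible cyclooxygenase, was at -1.63 and PTGES, a prostaglandin E synthase, at -2.28, while AKR1C1 was at 1.52, AKR1C3 at 1.18, PTGES2 at 0.66 and TBXAS1 at 0.52. STAT3 was at -0.66. In the same setting 56 of 72 ribosomal protein genes were higher and 0 lower, and the share of ribosomal protein reads of the 2 remaining knockdown libraries, 12.41% and 14.6%, exceeded that of each control library. In knockdown library 3 it was 6.47%. That library went the other way in several list sums. Integrin genes summed to 5370 CPM there against 4344, 4219 and 4831 CPM in control libraries 1, 2 and 3. EGFR genes summed to 2370 against 1868, 1808 and 2202 CPM. Heat shock genes summed to 7238 against 8643, 8666 and 7505 CPM, and G1/S genes to 2712 against 3254, 3219 and 3016 CPM. Stress response genes, at 8845 against 10672, 10625 and 9386 CPM, were lower there too.

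The first pattern was the rise of stromal genes among the 29, of which 6 lie on a fixed list, and for it RNA of another tissue in the knockdown libraries was set against a mesenchymal change of the cells themselves. A test with a bound of 1.2, planned once the called genes were known but before its own values were, went against outside RNA. The lowest knockdown library held 0.809 times the endothelial and 0.669 times the blood marker sum of the highest control library. But ESAM made up 72.3% and LYZ 97.6% of those control sums, so a small outside share could not have raised them and the bound was wrong. Likewise 0.25 of 8 endothelial and blood markers were lowest in knockdown library 2, against 0.362 of all tested genes. That was fewer than an outside source needed, though most of the 8 are expressed by these cells. A later test on 21 markers with few reads gave 1.19, just under its bound of 1.2. Its 95% interval, added once that value was known, was 0.83 to 1.71. That interval covers counting error only, leaves out the spread between libraries and so does not settle the bound. The ratio is set by knockdown library 2 (5.03 CPM). Knockdown libraries 1 and 3 held 11.04 and 11.82 CPM against 3.14 to 4.23 CPM in control libraries. This sum too held markers with reads in every control library, which hide a small outside share. CD14 had 28, 19 and 19 reads in control and 21, 14 and 16 in knockdown libraries 1, 2 and 3. HBB, although on the blood list, was left out of all 3 tests. None of the 3 tests met its criterion for outside RNA and none excluded it, while 25 of the 29 genes, HBB (166, 44 and 240 reads) and KDR (32, 7 and 42) were lowest in knockdown library 2 among the knockdown libraries, and PTPRC had 12, 1 and 70 reads; among the other called genes MUC16, an epithelial surface mucin, rose from 1.11 to 28.1 CPM, PGR, a nuclear receptor, from 1.22 to 30.5 CPM and PAEP, a secreted glycoprotein, from 0.62 to 10.5 CPM, all on no fixed list, and neither explanation was tested on them. A mesenchymal change may also account for the rise of stromal genes. For it, the epithelial junction median of -0.204 lay between the -0.3 called for and the -0.1 that would have spoken against it. The median was -0.398 without knockdown library 3 and -0.11 without knockdown library 1. A mesenchymal change also called for a blood marker sum, HBB left out, that overlaps between groups. That sum ran from 2081 to 2407 CPM in control and from 1611 to 1927 CPM in knockdown libraries, without overlap. The criterion for a mesenchymal change was thus not met, nor was the bound against it. LYZ made up most of the blood sum, so both explanations stay open.

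The second pattern was that libraries 3 stood apart from libraries 1 and 2 in both groups. Over 98.8% of the tested genes, Spearman's rho across genes between transcript length and the difference of library 3 from the other two was 0.184 in control and 0.227 in knockdown libraries, of the same sign but under the 0.3 set for a cause. For GC content it was 0.256 and -0.149, of opposite sign and smallest at 0.149. Genes are not independent replicates, and a difference in RNA quality or preparation could still lie behind it. The design names no biological difference between numbers, and none was tested.

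Over the 10 splits of the 6 libraries into 3 and 3, the real split gave 29 higher and 0 lower genes and the highest other split gave 0 in a direction, so 1 of the 10 splits reached the first count and all 10 the second. These fits took no account of the replicate numbers. Of the 10 splits, 4 part all 3 number pairs, and with the replicate block the real one of these gave 65 higher and 2 lower genes and the other 3 gave 0; the remaining 6 splits part 1 pair. Neither 10 nor 4 splits let the share fall under 0.05.

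In all, 14 genes with a median above 100 reads were listed at 0 in at least 1 library. Of these, 8 were at 0 in knockdown library 3, all of them mitochondrially encoded, among them MT-CO2 with 88996 reads in knockdown library 2 and MT-CYB with 34217. BARD1, with 351 reads in control library 2, was at 0 in knockdown library 2.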
